A study of Mus musculus with 6 samples.

How the data were processed

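Bulk RNA sequencing of mouse retinal ganglion cells was analysed from the gene tables the authors deposited, with 3 libraries from Tgfbr1-floxed mice carrying Vglut2-Cre and 3 from floxed mice without Cre. Per the labels' protocols, RNA was extracted with the RNeasy Micro kit and libraries were made from 1 ng of total RNA with the VAHTS Universal V6 kit. How the cells were isolated, the strand setting and the gene annotation are not given in the sources used here. Per the submitters' processing notes, fastp, HISAT2, HTSeq, R 3.2.0 and DESeq2 were used with the mm10 build, without a stated role for each. Where strand was not used, reads of overlapping antisense genes cannot be told apart, and reads shared with pseudogenes or paralogs, such as those of ribosomal proteins, make such genes uncertain.

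The deposited tables hold raw counts per gene and FPKM for the same 22413 genes, 1 column per sample, and there were 0 columns of other samples. The deposited FPKM equal the counts divided by a fixed gene length and the column total: the implied length varied between libraries by at most 6.4e-07 of its value, and 100% of lengths lay within 0.01 of a whole base. They carry no further scaling, so the counts were the main measure. No row lacked a gene name. Library totals were 11609621, 7486359 and 16372260 counts in controls 1 to 3 and 13936519, 21126291 and 8098891 in knockouts 1 to 3. A count of 0 allows up to 3 counts, 0.142 to 0.401 CPM per library. Lower bounds on folds use 3 counts over the group, and 95% intervals of ratios are exact binomial; both cover counting error only, since reads without molecular identifiers are not independent molecules.

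Knockout and control were compared with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, with genotype as the only term. DESeq2 1.42.0 and limma 3.58.1 (voom, voom with sample quality weights, and limma on log2(FPKM + 1)) were alternatives. DESeq2 gave no adjusted p for 16513 genes, which were left as missing. The low-count filter kept 5727 genes. Named genes followed a rule set before the data were examined: Tgfbr1 and Slc17a6; the 10 genes with the largest fold change in each direction past the threshold with a mean count of at least 20 and no overlap between genotypes, filled by the smallest unadjusted p in that direction under the same count limit where too few passed, as happened here; and up to 4 members of each list with the smallest p. Predicted genes and pseudogenes were left out by symbol. Eif2s3y and Ndufv2 were named outside the rule, after their values were seen. Some genes that the rule names are not reported here.

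The 35 gene lists, also fixed before the data were examined, covered TGF-beta signalling and targets, BMP targets, neurotrophic factors, injury response, axon growth, apoptosis, extracellular vesicles, synaptic release, ion channels, interferon, complement, matrix, oxidative phosphorylation, mitochondrially encoded and ribosomal proteins, immediate early genes, and markers of retinal, vascular and blood cells. Of 664 symbols with the sex-linked ones, 600 were in the table, and 13 mitochondrial genes were matched by a table of aliases. The 20 lists with at least 5 tested members were tested with camera (preset correlation 0.01) on voom values, with camera at an estimated correlation and fry beside it. Whether a list passed refers to camera at the preset correlation unless another test is named. Coordinates are from RefSeq GRCm38.p6, the assembly called mm10, in which 21198 table symbols were found.

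Detection means at least 10 counts. Libraries were also thinned without replacement to the smallest total. Detection patterns were compared with 1000 random tables that kept each gene's number of detecting libraries and each library's number of detected genes. Group values of a library measure were compared with exact two-sided permutation tests (Python 3.11.15). The count tests were tested on simulated data with the means and library sizes of these libraries and 200 changed genes; at a dispersion of 0.1 in place of the observed one, edgeR called 97 of 100 genes changed 4-fold and 100 of 100 changed 16-fold. Alternatives were other scalings, filters, tools, thresholds, FPKM settings, a replicate block, genes off chromosomes X and Y, and each library left out in turn.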

Results

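Retinal ganglion cells, the neurons whose axons form the optic nerve, were profiled by bulk RNA sequencing in adult mice with both copies of Tgfbr1 floxed. Tgfbr1 encodes the type I receptor for transforming growth factor beta (TGF-beta). In 3 samples the mice also carried a Vglut2-Cre allele, which places Cre recombinase under the gene for vesicular glutamate transporter 2 (Slc17a6), and these are called the knockout libraries. The other 3 samples came from floxed mice without Cre and are the controls. The libraries held 11609621, 7486359 and 16372260 gene counts in controls 1, 2 and 3, and 13936519, 21126291 and 8098891 in knockouts 1, 2 and 3. The labels do not say whether each sample was 1 animal or a pool, so p-values measure only the spread between these samples, which may be technical. The series places the comparison in work on neuroprotection by extracellular vesicles, and the question is which genes differ between ganglion cells with and without Cre on the floxed Tgfbr1 background. Expression is given as CPM, the counts scaled to the library's total, as mean ± SD over 3 libraries (n = 3), and log2 fold changes are knockout against control ± SE.

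The targeted gene, Tgfbr1 (mm10 chromosome 4, 47353222 to 47414926), had 1, 0 and 1538 counts in controls 1, 2 and 3 and 46, 0 and 793 counts in knockouts 1, 2 and 3. Its mean was 33.7 ± 55.6 CPM in the knockout and 31.3 ± 54.2 CPM in the control, a log2 fold change of 0.08 ± 3.38. The counts cover the whole gene and do not separate the floxed part, so this level does not check the labels. Its sign depended on the processing, and the value was 9.02 without control 3 and -3.94 without knockout 3. Slc17a6, the driver gene and a marker of ganglion cells (chromosome 7, 51621830 to 51671126), had 13572, 3498 and 0 counts in the controls and 5904, 13948 and 2101 in the knockouts, a log2 fold change of -0.27 ± 2.37. Its sign also turned, to 5.59 with voom, 1.64 to 2.74 on FPKM and 1.33 without control 1.

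Knockout libraries held more detected genes than control libraries. At 10 counts or more, 6738, 7209 and 5790 genes were detected in knockouts 1, 2 and 3, and 4258, 4463 and 4863 in controls 1, 2 and 3. The means were 6579 ± 722.7 and 4528 ± 307.7, a ratio of 1.45 (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). After every library was thinned to 7486359 counts the ratio was 1.44 (exact permutation p = 0.1). Which genes were detected differed widely within a genotype: of 11977 genes reaching 10 counts in some library, 3913 (32.7%) did so in 1 library and 1196 (10%) in all 6. The Pearson correlation of log2(CPM + 1) across genes, which are not independent replicates, was 0.57 to 0.62 between knockout libraries, 0.45 to 0.48 between control libraries and 0.50 to 0.57 between libraries of different genotype.

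**Figure D1:**
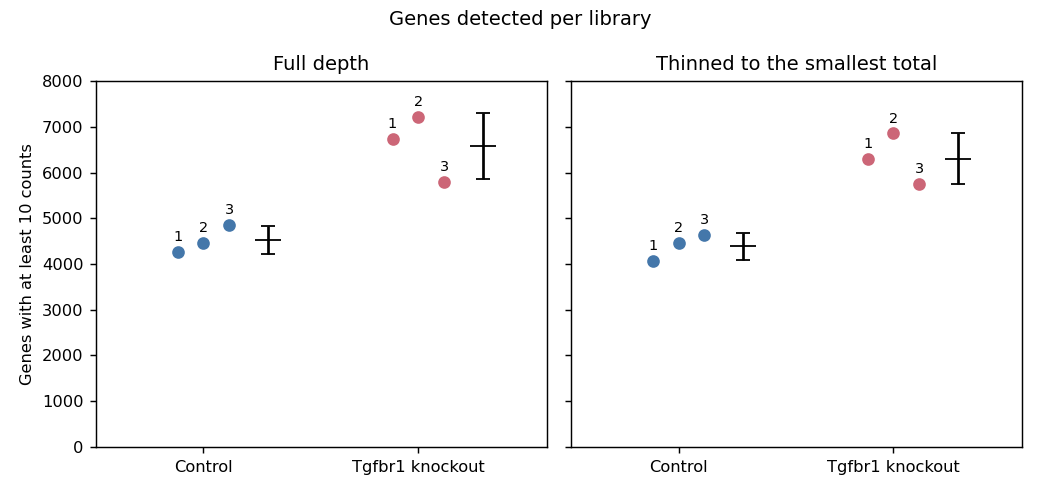
Genes with at least 10 counts in each library (points, numbered by replicate), with the mean and SD of each genotype (black bars), at full depth and after thinning every library to the smallest total. The 3 knockout libraries lie between 5790 and 7209 genes at full depth, all above the control libraries at 4258 to 4863.

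No gene passed the comparison of knockout and control. Of 5727 genes tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.681. At an unadjusted p under 0.05 there were 281 genes, 257 higher and 24 lower in the knockout (4.91% of those tested). An even spread of p-values would give 286. DESeq2 called 885 genes (744 higher, 141 lower) and limma voom 88 (82 higher, 6 lower), of which 77 were called by both. Of the DESeq2 calls, 859 (97.1%) were genes under 10 counts in all libraries of one genotype, and 0 were genes with 10 counts or more in all 6 libraries. Every knockout library lay above every control library for 593 tested genes (10.4%) and below for 132 (2.3%). Random labels give 5% in each direction for a single gene without ties. That rate is no test of these shares, since the genes come from the same 6 libraries and the knockout libraries detected more genes as a whole. The biological coefficient of variation was 2.04. On simulated counts with the dispersion of these 5727 genes, edgeR called 0 of 100 genes changed 4-fold and 6 of 100 changed 16-fold. The median log2 fold change of all tested genes was 0.14 with TMM scaling and -0.13 with DESeq2's size factors. With 1 library left out, edgeR called 7, 3 and 4 genes without controls 1, 2 and 3 and 2, 0 and 0 without knockouts 1, 2 and 3, all higher in the knockout except 1 of those without knockout 1.

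The genes with the smallest unadjusted p among those higher in the knockout were mostly near 0 in the controls, and 7 of the 10 had at most 4 counts over the 3 control libraries. None passed the adjusted threshold, and the values stand as measured. Rnf11, a RING finger protein, had 4402, 14780 and 2252 counts in the knockouts and 0, 1 and 1 in the controls, a ratio of depth-scaled group totals of 8810 (95% counting interval 2440 to 72700). It had the smallest unadjusted p of these genes in edgeR (0.000139). Rnf11 was called in each fit that left out 1 control and in none that left out 1 knockout. These fits reuse the libraries that picked the gene. Cisd2, an iron-sulfur protein of the endoplasmic reticulum and mitochondria, had 4, 0 and 0 control counts and 311 ± 348 CPM in the knockout. Several genes had 0 counts in every control: Wasf1, an actin regulator, was at least 2150-fold higher in the knockout, Dennd10 at least 2620-fold, Prelid3b at least 2200-fold, Nxt1, an mRNA export factor, at least 2170-fold, and Timm10, a mitochondrial import chaperone, at least 1960-fold. These bounds use a floor of 3 counts over the group and cover counting error only. Over the whole table, 274 genes were detected in all 3 knockouts and no control. Random tables with the same totals per gene and per library gave 248 to 305 (central 95%). The pattern was thus no more frequent than the detection rates of the libraries give. The rest of the 10 genes were measured in every library. Psma2, a proteasome subunit, was at 1080 ± 399 CPM in the knockout and 113 ± 96.5 CPM in the control (log2 fold change 3.51 ± 0.97). Cst3, the secreted protease inhibitor cystatin C, was at 1810 ± 574 against 642 ± 142 CPM (1.62 ± 0.51), and Celf2, an RNA-binding splicing regulator, at 868 ± 444 against 150 ± 49.6 CPM (2.66 ± 0.85).

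Fewer genes were lower in the knockout. Prnp, the prion protein, was at 217 ± 68.9 CPM in the knockout and 1040 ± 776 CPM in the control (-2.19 ± 0.78), with 31649 of its control counts in control 3, and its log2 fold change was -1.45 without that library. Txnl1, a thioredoxin-like protein, was at 132 ± 38.6 against 777 ± 207 CPM (-2.42 ± 0.94), and Pdcd4, an inhibitor of translation initiation, at 56.8 ± 47.0 against 703 ± 1090 CPM, with 32088 of its control counts in control 3 and a log2 fold change of -0.27 without it. Cavin2, a component of caveolae, Plekhh3 and Gramd1a had 0 counts in every knockout and were at least 781-fold, 533-fold and 424-fold lower. Dpy19l1, Gtf2e2, Crebl2 and Srcap, a chromatin remodeller, had 1, 1, 4 and 2 counts over the 3 knockouts and 173 ± 129, 155 ± 242, 180 ± 46.4 and 122 ± 138 CPM in the controls. None of these passed the adjusted threshold.

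**Figure D2:**
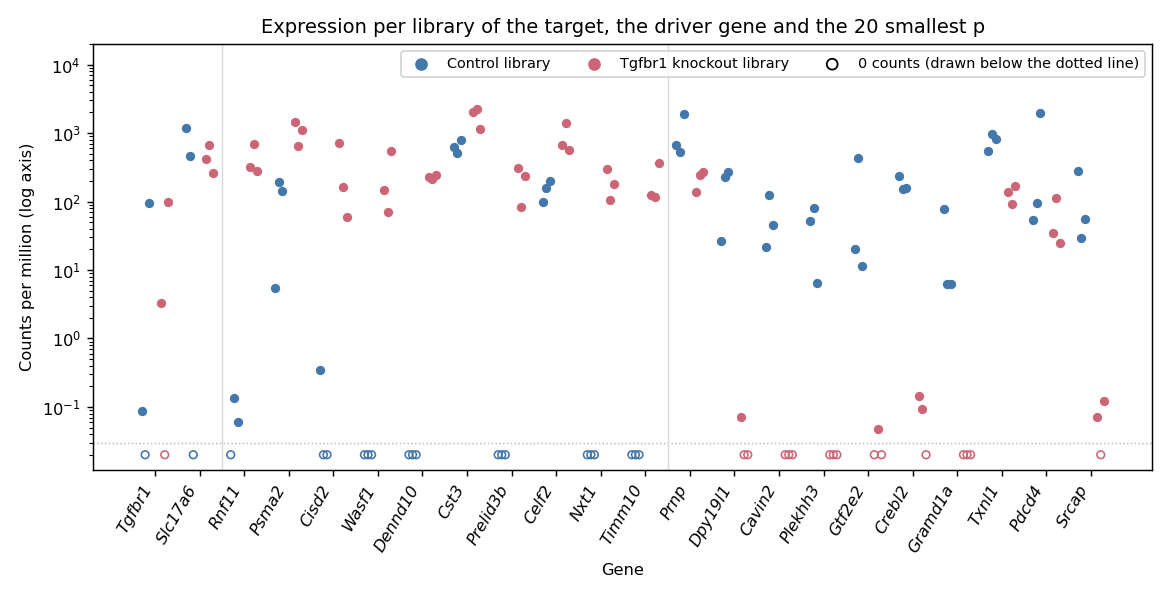
CPM on a log axis for Tgfbr1, Slc17a6, the 10 genes higher and the 10 lower in the knockout with the smallest p, 1 point per library, with libraries at 0 counts drawn as open circles below the dotted line. Tgfbr1 is at 0 counts in 1 library of each genotype, while Cst3, Celf2 and Psma2 are present in all 6.

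Nuclear genes of oxidative phosphorylation, the subunits of the respiratory chain and ATP synthase, ranked towards the knockout in camera with its preset correlation (adjusted p = 0.00793), the only one of 20 tested lists past 0.05, and did not pass with an estimated correlation (adjusted p = 0.795). List tests were run on voom values, where 27 of the 32 tested members were positive but the list's median log2 fold change, 0.88, lay below the 1.58 of all tested genes. The tallies of signs for all lists are from the edgeR fit, which gave 24 positive and 8 negative here, against 54.2% positive among all tested genes. No member passed, either over all genes or adjusted over the list alone, and 7 had an unadjusted p under 0.05, of which Ndufv2 of complex I was lower in the knockout, at 266.3 ± 257.4 against 1010 ± 230 CPM (-1.84 ± 0.82). Of the others, Uqcrb of complex III was at 2640 ± 297 CPM in the knockout and 1370 ± 51.8 in the control (1.07 ± 0.39), Ndufa4 at 3000 ± 324 against 1660 ± 275 (0.96 ± 0.38), Cox7a2 at 2450 ± 125 against 1260 ± 670 (1.07 ± 0.45) and Ndufb9 of complex I at 1350 ± 68.4 against 469 ± 318 (1.61 ± 0.66). Summed over the list, the libraries held 30470, 32610 and 26560 CPM in the knockouts and 25590, 25860 and 18380 in the controls (exact permutation p = 0.1). The knockouts detected 32, 32 and 31 of the 33 genes and the controls 28, 29 and 28. The list's adjusted p was 0.262 with DESeq2's size factors, 0.57 without control 3 and 0.0871 without knockout 2, and ran from 0.000198 to 0.795 over all alternatives.

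The proteins encoded by mitochondrial DNA did not pass (adjusted p = 0.684), and their direction turned with the library left out: the list passed as higher in the knockout without control 1 (adjusted p = 9.41e-08) and as lower without control 2, control 3 or knockout 1 (0.00617, 0.0261 and 0.0365). These calls are at the preset correlation, and none passed with an estimated correlation (adjusted p = 0.747, 0.691, 0.739 and 0.983 in the same order). Of 13 tested, 5 were positive in edgeR and 8 on voom values, and COX1 was at 7370 ± 2070 CPM in the knockout against 11200 ± 1170 in the control (-0.48 ± 0.28). Cytosolic ribosomal proteins were detected in nearly every library, 40 of 40 in 5 libraries and 39 in control 2 (adjusted p = 0.969), and Rpl38 was at 1450 ± 200 against 569 ± 447 CPM.

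Lists on TGF-beta signalling did not pass. Among receptors, ligands and SMADs, 10 of 17 tested genes had a positive log2 fold change and 0 had an unadjusted p under 0.05 (adjusted p = 0.929). Pmepa1, a TGF-beta-induced inhibitor of the pathway, had 2642, 1821 and 1418 counts in the knockouts and 1, 733 and 974 in the controls, and Tgif1, a SMAD corepressor, had 1600, 519 and 2297 against 1, 0 and 1060. Among TGF-beta target genes, 11 of 13 had a positive log2 fold change and 2 an unadjusted p under 0.05 (adjusted p = 0.324). Thbs1, which encodes thrombospondin 1, had 1342, 1513 and 233 counts in the knockouts and 0 in every control, at least 846-fold higher. Col3a1, a fibrillar collagen, had 985, 544 and 86 counts against 0, 0 and 2, and Acta2 of smooth muscle had 1, 231 and 0 against 0, 4089 and 2885. BMP target genes were too sparse to test: 5, 3 and 3 of 11 were detected in the knockouts and 1, 2 and 4 in the controls. Extracellular matrix genes had 7 positive and 7 negative log2 fold changes in edgeR and 10 and 4 on the voom values that were tested (adjusted p = 0.425). Without control 3 the list passed as higher in the knockout at the preset correlation (adjusted p = 0.0261) but not with an estimated correlation (adjusted p = 0.739).

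Of lists on survival and axon growth, none passed with camera. Among axon growth regulators 16 of 20 tested genes had a positive log2 fold change (adjusted p = 0.0917). Stmn2, a microtubule regulator of neurons, was at 1190 ± 415 CPM in the knockout and 267 ± 265 in the control (2.37 ± 0.80), and Gap43 of growth cones at 1480 ± 1070 against 694 ± 395 (1.27 ± 0.71). The injury and stress response had 13 of 17 positive (adjusted p = 0.615), with Sox11 at 973 ± 57.7 against 557 ± 386 CPM (0.88 ± 0.70). Of apoptosis genes, 10 were tested, 6 positive and 4 negative in edgeR and 10 positive on voom values, and 3 had an unadjusted p under 0.05 (adjusted p = 0.324, and adjusted p = 0.795 with an estimated correlation). Among these, Bax had 12, 65 and 684 counts in the knockouts and 0 in every control, and Cycs was at 1060 ± 167 against 424 ± 138 CPM. Fry, which tests whether a list's genes move one way on balance, passed apoptosis alone (adjusted p = 0.00725). Its mixed form, which ignores direction, passed 8 of the 20 lists. These were apoptosis, neurotrophic factors and receptors, mitochondrially encoded proteins, complement and inflammation, TGF-beta target genes, oxidative phosphorylation, axon growth regulators and extracellular matrix. Both forms work on the voom values and do not compare a list with other genes. On those values the median log2 fold change of all tested genes was 1.58, so upward values were not particular to apoptosis. Of neurotrophic factors and receptors, 5 of 8 were positive in edgeR and 3 on voom values (adjusted p = 0.929). Ret, the receptor subunit for the GDNF family, had 414, 1539 and 405 counts in the knockouts and 0 in every control, at least 646-fold higher, Bdnf had 2712, 8525 and 1542 against 9, 2070 and 0, and the neurotrophin receptor Ntrk3 had 156, 0 and 0 against 571, 6 and 1. Beside these counts stands the detection of more genes in every knockout library, which applied to the table as a whole.

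The remaining pathway lists did not pass. Extracellular vesicle biogenesis and uptake had 9 of 24 tested genes positive in edgeR and 15 on voom values (adjusted p = 0.494), with the vesicle tetraspanin Cd63 at 930 ± 548 CPM in the knockout and 587 ± 223 in the control, and the vesicle adaptor Sdcbp lower, at 651 ± 57 against 1340 ± 1550 CPM (-0.89 ± 0.70), with 50839 of its control counts in control 3, without which its sign turned. Neuronal ion channels had 10 of 10 positive (adjusted p = 0.542), among them the sodium channel Scn8a at 1186, 82 and 910 counts against 5, 0 and 22. Synaptic vesicle genes had 6 of 14 positive in edgeR and 10 on voom values (adjusted p = 0.923), interferon response and antigen presentation 3 of 6 (0.795), and immediate early and dissociation genes 9 of 14 (0.923). Without control 1 the interferon list passed as lower in the knockout at the preset correlation (adjusted p = 0.0309) but not with an estimated correlation (adjusted p = 0.747). Complement and inflammation had 2 of 5 positive in edgeR and 3 on voom values (0.324). Adjusted over the list alone, 1 member of that list passed and 0 members of the other lists tested, and over all genes tested 0 members of any list passed.

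Ganglion cell markers were present in both genotypes, unevenly between libraries. Of 21 pan-ganglion cell markers, 12, 14 and 12 were detected in knockouts 1, 2 and 3 and 12, 11 and 8 in controls 1, 2 and 3, with summed levels of 4829 ± 819 and 4126 ± 1340 CPM (exact permutation p = 0.7). Sncg, a synuclein of ganglion cells, was at 1250 ± 685 against 913 ± 667 CPM. Subtype markers were detected at 5, 9 and 3 of 21 in the knockouts and 5, 2 and 4 in the controls, and Spp1 alone ranged from 4 counts in control 2 to 156336 in knockout 1. Of 14 endothelial markers, controls 1, 2 and 3 detected 6, 1 and 13 and knockouts 1, 2 and 3 detected 6, 6 and 10. Control 3 stood apart by their level, at a summed 8225 CPM, where the other 5 libraries held 36.07 to 927.2 CPM. It had 23749 counts of Cdh5, 15258 of Flt1, 14557 of Tek and 10918 of Pecam1, and 0 of Slc17a6. Endothelial markers had 8 of 9 negative and did not pass (adjusted p = 0.324), passed as lower in the knockout without control 2 at the preset correlation (adjusted p = 0.0024, and adjusted p = 0.691 with an estimated correlation), and without control 3 the fitted fold changes of Cdh5, Flt1, Tek and Pecam1 turned positive. Vim, shared by the Müller glia and horizontal cell lists, had 96054 counts in control 3 and 9734 to 14198 in the others.

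Markers of other cell types varied in level between libraries. Amacrine markers were detected at 7, 7 and 5 of 17 in the knockouts and 2, 3 and 2 in the controls, with 574.7 ± 268.8 against 366.3 ± 88.55 CPM summed (exact permutation p = 0.3). Müller glia (8, 8 and 6 against 6, 8 and 7 of 15, summing to 1779 ± 957.7 CPM in the knockout and 4186 ± 2860 in the control; adjusted p = 0.324) and horizontal cell markers (7, 8 and 5 against 5, 3 and 6 of 9, summing to 2094 ± 243.2 and 3184 ± 2961 CPM; adjusted p = 0.929) did not pass. In control 3 Vim alone was at 5870 of the 7258 CPM of the Müller glia list and of the 6603 CPM of the horizontal cell list. Bipolar markers summed to 172.0 ± 15.08 CPM in the knockout and 295.6 ± 440.4 in the control, rod markers to 470.1 ± 287.0 and 822.9 ± 627.8, mostly from Gnb1, and cone markers to 29.75 ± 33.04 and 431.5 ± 746.9, mostly from Gngt2. Astrocyte markers summed to 278.2 ± 184.1 and 306.4 ± 96.68, microglia to 168.6 ± 145.6 and 61.04 ± 67.01, pericyte and smooth muscle to 317.8 ± 245.5 and 345.7 ± 300.5, and fibroblast to 75.72 ± 98.77 and 136.6 ± 119.7. Pigment epithelium markers summed to 15.31 ± 17.78 and 36.13 ± 61.86, oligodendrocyte to 45.98 ± 67.95 and 8.142 ± 8.722, and lens crystallins to 124.3 ± 16.74 and 608.8 ± 829.0, from Cryab. Leukocyte markers stood at 1099 CPM in knockout 1 and at most 128.8 CPM elsewhere, and red blood cell markers were at 0 in every library except knockout 1, with 0.9328 CPM.

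**Figure D3:**
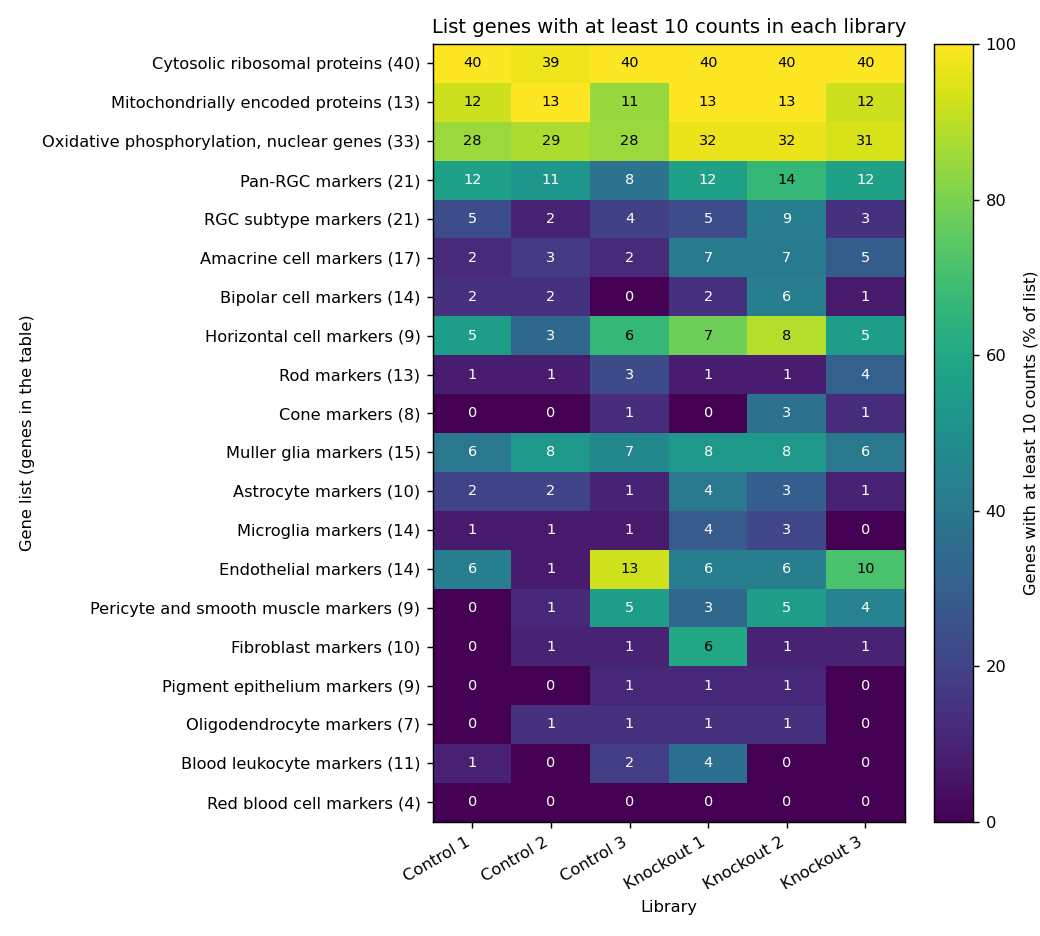
Number of genes with at least 10 counts in each library (cell text) for 20 gene lists, colored by the percent of the list's genes in the table, which the row label gives in parentheses. Ribosomal protein genes are detected at 39 to 40 of 40 in all 6 libraries. Endothelial markers are detected at 1 (control 2) to 13 (control 3) of 14.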

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

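The detection counts, their thresholds, the restriction to genes detected in all 6 libraries and the estimated correlation beyond the main setting were chosen after seeing the data, and the other settings before. With edgeR, 0 genes passed under DESeq2's size factors, library size alone, both other count filters, no robust dispersion, genes off chromosomes X and Y, a 2-fold limit, and over the 1196 genes detected in all 6 libraries (25 at an unadjusted p under 0.05); limma on FPKM also gave 0 under each of its 3 settings. DESeq2 gave 885 genes (744 higher, 141 lower), limma voom 88 (82 and 6) and voom with sample quality weights 6 (2 and 4). An unadjusted p under 0.05 with a 2-fold limit gave 280 genes (256 higher, 24 lower). Leaving out 1 library gave 0 to 7 genes, 0 to 7 higher and 0 to 1 lower: 7 without control 1, 3 without control 2, 4 without control 3, 2 without knockout 1, and 0 without knockout 2 or knockout 3. The cause was not tested.

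The log2 fold change of Tgfbr1 reversed to -0.20 with DESeq2's size factors, -0.02 without a count filter and -0.22 with DESeq2, and ran from -3.94 to 9.02 when 1 library was left out (-0.56 without control 1, -0.50 without control 2, -3.94 without knockout 3). Slc17a6 reversed to 5.59 with voom, 4.47 with quality weights, and 1.64, 2.74 and 1.64 on FPKM with a pseudocount of 1, of 0.1, and of 1 with a filter, and ran from -0.91 to 1.33 (without control 1) when 1 library was left out. Cdh5 reversed to 1.04 with quality weights and to 0.25, 0.81 and 0.25 on FPKM, and with quality weights Flt1 reversed to 1.52 and Pecam1 to 0.53. With 1 library left out, Tek ran from -12.36 to 1.17, Cdh5 from -2.49 to 0.64, Flt1 from -5.01 to 6.92, Pecam1 from -4.27 to 0.06, Vim from -1.68 to 0.02 and Sdcbp from -1.42 to 0.72, each positive only without control 3. Ntrk3, which has no value without knockout 1, ran from -2.72 to 3.68 in the other such fits, positive only without control 1. Spp1 ran from -0.20 to 2.77 and Smurf2 from -1.74 to 9.16, each negative only without knockout 1. The cause was not tested.

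The count of lists past an adjusted p of 0.05 was 0 without a count filter, 0 with an estimated correlation and 0 to 3 when 1 library was left out (3 without control 1, 3 without control 2, 2 without control 3, 2 without knockout 1, 0 without knockout 2). Beside oxidative phosphorylation these were interferon response (lower, adjusted p = 0.0309) without control 1, endothelial markers (lower, 0.0024) without control 2, extracellular matrix (higher, 0.0261) without control 3, and mitochondrially encoded proteins, higher without control 1 (9.41e-08) and lower without control 2 (0.00617), control 3 (0.0261) or knockout 1 (0.0365). With DESeq2's size factors the list that passed was mitochondrially encoded proteins, lower in the knockout (6.44e-09). These calls are at the preset correlation, and 0 lists passed with an estimated correlation in any of these settings. Genes detected in all knockouts and no control numbered 274, and 456 to 668 when 1 library was left out (456, 512 and 582 without controls 1, 2 and 3, and 558, 475 and 668 without knockouts 1, 2 and 3), since fewer libraries then have to share the pattern. Genes detected in all controls and no knockout numbered 16, and 90, 83 and 71 without controls 1, 2 and 3, and 33, 53 and 36 without knockouts 1, 2 and 3.

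No pairing of the samples by replicate number was seen, but the check could miss one given the wide spread within each genotype. Deviations of same-numbered samples from their group means correlated at -0.025, 0.028 and -0.009, and 1 of 3 controls correlated best with its own number. Whether the numbers pair the samples stays undetermined. With a replicate block edgeR called 0 genes (197 at an unadjusted p under 0.05), Slc17a6 reversed to 1.49 and Cdh5 to 0.13, and the list that passed was again mitochondrially encoded proteins (adjusted p = 0.0178, and adjusted p = 0.85 with an estimated correlation).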

Other observations

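The tests on sex-linked reads were chosen after their values were seen, and the detection counts and their thresholds were chosen after seeing the data; the other tests were set before. With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes with edgeR, and the highest of the others gave 2. A count of at least 0 is reached by 10 of 10 splits whatever the data, so this comparison can decide nothing. At an unadjusted p under 0.05 edgeR gave 281 genes in the real split and 123 to 196 in the others. With DESeq2 it gave 885 and the highest other 689, and with voom 88 and 23, so that 1 split, the real one, gave as many. For gene lists it gave 1, the highest other gave 8, and 9 of the 10 splits gave at least 1.

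DESeq2 called 885 genes where edgeR called 0. The 9 splits that mix the genotypes gave 529 to 689 DESeq2 calls, at most 77.9% of the real count. On simulated counts with the dispersion of these 5727 genes, DESeq2 called 207 unchanged genes. A candidate explanation for most of the count is all-or-none counts between libraries, whatever the genotype. The simulation tested the tool at this dispersion and not that explanation. Each mixed split still held the genotypes unequally on its sides, so its calls are not free of a genotype effect. What makes the real split higher than 689 stays open, and genotype is among the open explanations.

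Genes detected in all 3 knockouts and no control numbered 274, and those detected in all 3 controls and no knockout 16 (456 to 668 and 33 to 90 when 1 library was left out). Sequencing depth is argued against, since at equal depth the lowest knockout library still held 1.237 times the genes of the highest control library. A higher detection rate of the knockout libraries for all genes may account for the count: random tables with the same totals per gene and per library gave a mean of 277.0 (central 95% from 248 to 305). The count was 0.99 times that mean. The ratio was 0.98 at a limit of 3 counts, 1.08 at 100 counts and 1.05 at equal depth, each count within its central 95%. Both patterns together numbered 290 in the real split and at most 232 in the others. An effect of genotype on these genes in particular cannot be told apart from the higher detection rate, which itself goes with genotype in this design. Why knockout libraries held more genes was not tested.

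Many genes had 1000 counts or more in one library and under 10 in another of the same genotype. Of comparisons within genotype in which a gene had 1000 counts or more in one library, 30.1% had under 10 in the other. The share ran from 12.9% to 28.6% between knockout libraries and from 33.1% to 47.3% between control libraries. Depth is argued against, since thinning to the smallest total, with both limits applied again, left 0.865 of the 30.1%. Different cell types in each library might be a source. This was weighed on a broader measure, the share of libraries of both genotypes with under 10 counts, without the limit of 1000 counts. By it, genes that every cell uses went missing 0.59 times as often as other genes of the same mean abundance (0.46 to 0.79 over the central 95% of matched gene sets). That lies between the bounds set for and against this explanation, so it stays open, together with loss of molecules from a small RNA input, which was not tested.

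Flanking DNA of the Vglut2-Cre allele was tested as a hypothesis: the 40 tested genes within 10 Mb of Slc17a6 had a median absolute log2 fold change of 1.41, against 1.16 over all genes, at percentile 78.9 of windows of as many neighbouring genes, which leaves the hypothesis open. The 50 genes around Tgfbr1 were at 1.03 and percentile 24.2, but all the mice carry the floxed allele, so the comparison of genotypes cannot test flanking DNA there whatever its value, and the bound set for it beforehand was wrong for that reason. With edgeR, 0 genes of either window were called.

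Xist, transcribed from the inactive X chromosome of females, and Y-linked reads occurred in the same libraries. Control 1 had 4426 counts of Xist and 1759 of Eif2s3y, control 2 had 1535 of Xist and 513 of Uty, knockout 1 had 9595 of Xist and 967 of Ddx3y, and knockout 2 had 8912 and 2731. The Y-linked gene given is the highest in each library. Ddx3y and Uty were at 0 in control 1, Ddx3y and Eif2s3y in control 2, and Eif2s3y in both knockouts. In control 2 and knockouts 1 and 2 the smaller signal was at least 7.04% of the same gene's counts in all other libraries together. Eif2s3y of control 1 had 0 counts in every other library. Both argue against reads carried over between libraries in these 4. In control 3 (5 of Xist, 10953 of Ddx3y) and knockout 3 (4323 and 48) the smaller signal was at most 0.328%, a level that carry-over could give. Whether samples pooled mice of both sexes was not tested.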
